A study of Mus musculus with 3 samples.

How the data were processed

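The 3 arrays were of 1 design with 60-base probes, hybridised with Cy3-labelled RNA (200 ng of total RNA per labelling, per the labels) and read with Agilent Feature Extraction 11.5.1.1. Per the file headers, gProcessedSignal is an intensity on a linear scale, background-subtracted and detrended within the array and not scaled between arrays; gMeanSignal and gBGMedianSignal are likewise intensity values per the file headers. The deposited value table of the authors holds a linear ratio, which matches the processed intensity divided by the 75th percentile of the array (quotients constant to within a tolerance of 0.001). Column medians were 0.0524 for vehicle, 0.0500 for the epoxide sample and 0.0413 for GW9662. The vehicle column matches its own scanner file, while the columns of the treated samples match each other's scanner files, and the labels do not settle which is right. The scanner files as attached to the samples were used, with the value table as an alternative.

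For each array, log2 gProcessedSignal was reduced by the log2 of the 75th percentile over non-control spots. Spots marked as non-uniform or as population outliers (230, 221 and 251 on the vehicle, epoxide and GW9662 arrays) were left out, copies of a probe were averaged, and no spot was saturated. Probes were named through the RefSeq gene table where their accession is in it (28330 of 39429 probes, 1403 with a changed symbol) and by the file's gene name otherwise. Probe coordinates are those of the files (mm9). A gene was read by its probe with the highest mean level over the 3 arrays, counted as measured when most copies were well above background on both arrays, and called when the ratio was at least 2-fold. With 1 array per group no test was possible. The SD among copies of a probe, median over 220 probes detected on all arrays, was 0.0603, 0.0561 and 0.0555 on the vehicle, epoxide and GW9662 arrays, which gives a technical SD of a log2 ratio of 0.0824, 0.0820 and 0.0789 for the 3 comparisons (epoxides over vehicle, GW9662 over vehicle and epoxides over GW9662). It covers spot error only, not culture, labelling or hybridisation. Log2 ratios of the 10 labelled spike-in probes ran from -0.75 to 0.12 for epoxides over vehicle and from -0.18 to 0.04 for GW9662 over vehicle. The ends of both ranges are spike-ins below the lowest level called well above background on the vehicle array (-4.84). The spike-ins at -1.68 or more with vehicle ran from -0.37, in the brightest of them, to 0.05 for epoxides over vehicle. For GW9662 over vehicle they were all negative, from -0.17 to -0.10.

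The gene lists (39, with 815 genes, 812 of them found), the comparisons, the rule for named genes and the alternatives were fixed before the data were examined. For each list with at least 5 measured genes, the median log2 ratio was placed among 10000 random lists of the same size matched on signal in 20 bins. The text describes every list outside the middle 95% and others that bear on mast cells, ribosomes and PPAR gamma, a selection made after their values were seen. Genes named in each comparison were the up to 10 highest and 10 lowest with a plain symbol, at least 2-fold apart, with the brighter array at or above the median signal of detected probes and every other detected probe going the same way; the up to 4 members farthest from 0 of each list described; Pafah2, Pparg, Srcin1, Kit, Fcer1a, Ms4a2 and Fcer1g; and the 3 largest bounds in each direction. A bound sets the dimmer array at the higher of its own level and the lowest level called well above background there.

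Alternatives were normexp background correction (offset 50, limma 3.58.1 in R 4.3.3), quantile normalization, cyclic loess, scaling on probes above background on all arrays, the authors' value table, the mean of a gene's detected probes, no filter on dim probes, only genes at or above the median signal, and 1.5-fold in place of 2-fold for counts. After the data were seen, 3 alternatives were added: without rows 181 to 400 of 532, with a quadratic trend in probe GC content and mean signal removed from each array, and both together. The rows are the bands of 20 rows in which at least 2% of the copies of probes with 5 or more copies lay 2-fold or more from the median of their probe. In 1 test, each array was also only shifted by its mean deviation over detected probes, or cleared of a trend in GC content alone or signal alone. The pixel CV of a spot is the SD of its pixels over its mean signal. The rule for rows was itself chosen after the values were seen. A first version, restricted to probes detected on all arrays with outlier spots left out, marked no rows. Over all copies, 7.69% of readings inside these rows and 0.589% outside were off by that much. For probes detected on all arrays the shares were 0.393% (11 of 2799) and 0.0263% (1 of 3801), and with outlier spots left out 1 of 2735 and 0 of 3753. The disagreement thus sits mainly in dim or marked copies. Rows 181 to 400 hold 41.9% of the non-control spots.

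The steps were tested on simulated data. Errors were drawn from copies of probes of like signal, in 5 bins, inside or outside rows 181 to 400, and 50 genes each were changed by a known fold. For epoxides over vehicle (15818 genes), 2.00% of genes changed 1.5-fold were called, 48.0% of those changed 2-fold, 100% of those changed 3-fold and 100% of those changed 4-fold. For GW9662 over vehicle (15792 genes), these shares were 2.00%, 44.0%, 98.0% and 100%. In 20 sets of unchanged arrays, a mean of 131.6 genes were called higher and 105.8 lower for epoxides over vehicle, and 126.2 higher and 92.8 lower for GW9662 over vehicle. For epoxides over GW9662 the means were 98.0 higher and 109.6 lower. The simulated calls outnumber the measured ones for GW9662 over vehicle in both directions and for genes higher in both comparisons of epoxides, so the simulated errors are too large for these. A first version drew errors by row without regard to signal and gave means of 552.0 higher and 514.6 lower for epoxides over vehicle; it was replaced for that reason. Of 100 unshifted lists of 25 genes, 5 and 10 fell outside the middle 95% in the 2 comparisons, and lists shifted by 0.3 reached percentile 100 in both. Python 3.11.15, numpy 2.4.6 and pandas 2.3.3 were used, with matplotlib 3.10.9 for figures.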

Results

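Total RNA from bone-marrow-derived mast cells (BMMCs, mast cells grown out of bone marrow progenitors) of male mice lacking Pafah2 was measured on 3 one-colour microarrays. Pafah2 is a phospholipase A2 that releases oxidised fatty acids from phospholipids. There was 1 array for cells given vehicle (DMSO), 1 for cells given a mixture of the omega-3 fatty acid epoxides 17,18-EpETE and 19,20-EpDPE (300 nM in a ratio of 2 to 3), and 1 for cells given GW9662 (0.5 µM), an antagonist of the nuclear receptor PPAR gamma. All treatments lasted 12 h. There were no replicates, so the error between cultures could not be estimated and no test was possible. Of 43020 non-control spots, 22489 (52.3%) were well above background on the vehicle array, 23472 (54.6%) on the array labelled omega-3 epoxides and 22918 (53.3%) on the array labelled GW9662. Levels are log2 signals relative to the 75th percentile of the array, and ratios are differences of these levels.

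The treated arrays cannot be assigned to a treatment with certainty. In the authors' value table the column of the epoxide sample holds the values of the scanner file attached to the GW9662 sample, and the GW9662 column holds those of the epoxide scanner file. The arrays are named here by the sample to which their scanner files are attached. Where the value table is right instead, every statement on 1 treated array belongs to the other treatment.

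Fcer1a, the IgE-binding chain of the high-affinity IgE receptor, had a level of 6.93 with vehicle, 6.59 on the array labelled epoxides and 6.83 on the array labelled GW9662. Fcer1g, the receptor's signalling gamma chain, had levels of 6.43, 6.05 and 6.37 in the same order, and Ms4a2, its beta chain, had 3.65, 3.75 and 3.70. Kit, the receptor for stem cell factor, had 5.73, 5.68 and 5.75. Pparg, the target of GW9662, was dim but above background, at -3.75, -4.39 and -3.94. Pafah2 was read at 0.03, -0.08 and 0.07 by 1 probe on chromosome 4 (mm9 133982528 to 133982587). The labels do not say which part of the gene was deleted and no wild-type array was included, so this signal says nothing on the deletion.

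The first comparison asked which transcripts differ when cells without Pafah2 are given omega-3 epoxides. On the array labelled epoxides, Kdr, the receptor VEGFR2 for vascular endothelial growth factor, was lower than with vehicle, with a log2 ratio of -1.22 (2.32-fold). It was the only gene that met the rule for named genes, which asks for a bright signal, a 2-fold difference and the same direction in the gene's other detected probes. Immediate early genes, which are transcribed soon after a stimulus, had negative ratios in 17 of 20 measured members, with a median of -0.20 that lay at percentile 4.17 of random lists of like signal and was between -0.09 and -0.12 with quantile normalization, with cyclic loess and with the trend in GC content and signal removed. Among them were Klf2, a Krüppel-like transcription factor, at -0.62, the AP-1 subunits Junb at -0.57 and Fosb at -0.56, and Dusp1, a phosphatase of MAP kinases, at -0.52. No list median of the 35 that could be placed lay outside the middle 95% of its random lists.

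Mast cell granule proteases had a median of -0.24 over 13 genes (percentile 9.54), with Cpa3, a carboxypeptidase, at -0.68, the chymases Cma1 at -0.39 and Cma2 at -0.40, and the lysosomal protease Ctss at 0.43. That median was -0.06 with quantile normalization, -0.12 with cyclic loess and -0.10 with the trend in GC content and signal removed. Mast cell identity genes had a median of -0.10 over 24 genes (percentile 93.0), positive with quantile normalization and with the trend in GC content and signal removed. Their members farthest from 0 were Csf2rb, the shared beta chain of cytokine receptors, at -0.40, Tph1, an enzyme of serotonin synthesis, at -0.38, and Fcer1g and Fcer1a at -0.38 and -0.34. Ribosomal protein genes had a median of -0.30 over 30 genes (percentile 10.9), with Rps18 at -0.54, Rplp1 at -0.53 and Rpl18 at -0.46. That median was -0.038 with quantile normalization and -0.016 (percentile 50.1) with the trend in GC content and signal removed.

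IgE receptor signalling genes had a median of -0.07 over 33 genes (percentile 58.9), positive with quantile normalization and cyclic loess. Its members farthest from 0 were Sphk1, a sphingosine kinase, at -0.62, Fcer1g and Fcer1a, and the Src-family kinase Lyn at 0.30. Without rows 181 to 400 the ratios of this list ran from -0.34 to 0.30, so those of Sphk1 and Fcer1g rest at least partly on those rows. The 28 measured negative regulators of the IgE receptor and of Src kinases had a median of -0.01 (percentile 83.3), which was positive with normexp, quantile normalization, cyclic loess, scaling on detected probes and the trend in GC content and signal removed, with or without rows 181 to 400. They included Csk, the kinase that inactivates Src-family kinases, at 0.60, Cd300a, an inhibitory receptor, at 0.33, and Lilrb4a, an inhibitory receptor, at -0.45. PPAR gamma target genes had a median of -0.06 over 14 genes (percentile 50.5), with the glycerol channel Aqp7 at -0.77, Pparg itself at -0.64, the lipid droplet protein Plin4 at -0.62 and the acyl-CoA synthetase Acsl1 at 0.18. Outside rows 181 to 400, genes in the dimmest of 10 signal bins had a median of -0.35 (first quartile -0.70). The ratio of Pparg, a dim gene, was thus not told apart from a shift at low signal. The PPAR gamma median was 0.01 among genes at or above the median signal and 0.0002 with the trend with probe GC content and signal removed, where Plin4 came to 0.02.

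Over the 15819 genes measured on both arrays, 34 were at least 2-fold higher and 328 at least 2-fold lower on the array labelled epoxides. The genes higher made up 9.39% of these calls, 30.9% with quantile normalization and 22.9% with cyclic loess. Of the genes lower, 210 were read in rows 181 to 400 of the array, where copies of the same probe disagreed most, and outside these rows the ratio fell with the share of G and C bases in the probe (r = -0.558 across genes, which are not independent replicates). With those rows left out and the trend with GC content and signal removed, 22 genes were higher and 20 lower, and the ratio of Kdr was -0.95. Immediate early genes then lay at percentile 0.55, granule proteases at 1.89 and genes of G2 and M phase (median 0.12) at 97.9, outside the middle 95%.

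**Figure D1:**
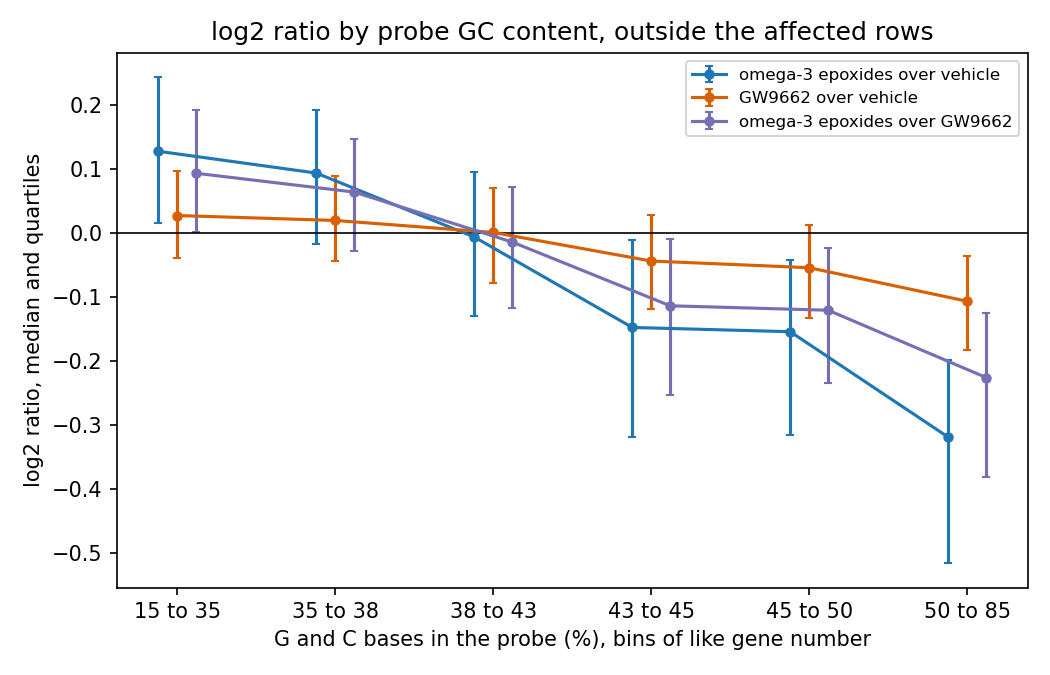
Median log2 ratio (points, bars from the first to the third quartile) of genes read outside rows 181 to 400, in 6 bins of the percentage of G and C bases in the probe, for the 3 comparisons. For the array labelled epoxides over vehicle the median goes from 0.13 in the bin with the fewest G and C bases to -0.32 in the bin with the most, and for the array labelled GW9662 over vehicle from 0.03 to -0.11.

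The second comparison asked which transcripts differ when cells are given the PPAR gamma antagonist. On the array labelled GW9662, immediate early genes lay below vehicle: 15 of 19 measured members had negative ratios, and the median of -0.43 lay at percentile 0 of the 10000 random lists. Klf2 was lower with a log2 ratio of -1.06 (2.08-fold), Dusp1 had -0.69, and the zinc finger factors Egr2 and Egr1 had -0.68 and -0.62. Klf2 was read in rows 181 to 400. Without those rows the ratios of this list ran from -0.69 to 0.29, with a median of -0.42 (percentile 0). Of 23 measured fatty acid oxidation genes, 14 had positive ratios, with a median of 0.10 (percentile 100) that was 0.054 with no filter on dim probes, 0.060 with the mean of a gene's probes and 0.062 without rows 181 to 400 (percentiles 99.8, 99.9 and 99.4). Of these, Cyp4a10, a fatty acid omega-hydroxylase, was higher with a ratio of 1.21, Cpt1a, which makes the acylcarnitines that enter mitochondria, had 0.83 (1.78-fold), and Slc25a20, the carnitine-acylcarnitine carrier, and Hadh, a dehydrogenase of beta-oxidation, had 0.26 and 0.24. The only genes that met the rule for named genes among those higher were Cyp4a12a (1.53, 2.89-fold) and Cyp4a12b (1.40, 2.63-fold), further fatty acid omega-hydroxylases of the Cyp4a cluster on chromosome 4 (mm9 115005258 to 115005317 and 115111580 to 115111639).

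The medians of 5 further lists also lay outside the middle 95% of random lists. Cytokines and chemokines had a median of -0.16 over 22 genes (percentile 0), with the chemokines Ccl1 at -1.40, Ccl4 at -0.53 and Ccl7 at -0.39 and the cytokine Osm at -0.49. Genes of the NRF2 oxidative stress response had a median of 0.07 over 24 genes (percentile 100), with the glutathione transferase Gsta3 at 0.44, Gclm, a subunit of the enzyme that starts glutathione synthesis, at 0.30, the quinone reductase Nqo1 at 0.25 and Osgin1 at -0.24. Without rows 181 to 400, ratios ran from -0.13 to 0.18 for NRF2 genes and from -0.49 to 0.17 for cytokines and chemokines. The values of Ccl1, Ccl4 and the NRF2 members named thus rest at least partly on spots in those rows. The medians without the rows were 0.07 for NRF2 genes and -0.14 for cytokines and chemokines. Genes of S phase had a median of -0.10 over 21 genes (percentile 0.19), with thymidylate synthase Tyms at -0.20 and the replication factors Gins2 and Mcm3 and the transcription factor E2f1 each at -0.18. Genes of G2 and M phase had a median of 0.06 over 24 genes (percentile 99.8), with the kinases Ttk at 0.19 and Cdk1 at 0.14, the motor protein Kif11 at 0.15 and cyclin Ccnb2 at -0.13. Genes of hypoxia and glycolysis had a median of -0.08 over 23 genes (percentile 1.1), with lactate dehydrogenase Ldha at -0.17, the growth factor Vegfa at -0.16, and the collagen hydroxylase subunits P4ha2 at -0.16 and P4ha1 at -0.14. These 7 lists of the 36 placed describe 1 pair of arrays, and among their measured members only Klf2, Ccl1 and Cyp4a10 differed by 2-fold or more. With the trend in GC content and signal removed the percentiles were 9.47 for hypoxia and glycolysis and 95.5 for G2 and M phase, and without rows 181 to 400 they were 3.15 for S phase, 2.78 for hypoxia and glycolysis and 96.1 for G2 and M phase, all inside the middle 95%, while with both changes they were 0.37 for S phase, 1.63 for hypoxia and glycolysis and 98.6 for G2 and M phase, and the cytokine median was -0.10. Also inside were hypoxia and glycolysis with cyclic loess (4.28) and with the mean of a gene's probes (13.2), G2 and M phase among genes at or above the median signal (96.5) and cytokines and chemokines with no filter on dim probes (2.78).

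Mast cell identity genes had a median of -0.06 over 24 genes (percentile 14.2), with the serotonin transporter Slc6a4 at -0.29, histidine decarboxylase Hdc at -0.22, the interleukin 3 receptor chain Il3ra at -0.15 and the adaptor Lat2 at 0.15. IgE receptor signalling genes had a median of -0.03 over 33 genes (percentile 44.2). Their ratios ran from -0.48 to 0.38, with Sphk1 at -0.39 and the adaptor Lcp2 at 0.38 among them. Ratios without rows 181 to 400 ran from -0.15 to 0.02 for mast cell identity and from -0.13 to 0.28 for IgE receptor signalling. The values of Slc6a4, Hdc, Lat2, Sphk1 and Lcp2 thus rest at least partly on spots in those rows. The medians without the rows were -0.08 for mast cell identity and -0.02 for IgE receptor signalling. PPAR gamma target genes had a median of -0.05 over 14 genes (percentile 28.7), with lipoprotein lipase Lpl at 0.24, Aqp7 at -0.21, Pparg at -0.19 and the lipase inhibitor Angptl4 at 0.15. In this comparison the dimmest of 10 signal bins had a median of -0.13 (first quartile -0.23), so the ratio of Pparg may be a shift at low signal.

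**Figure D2:**
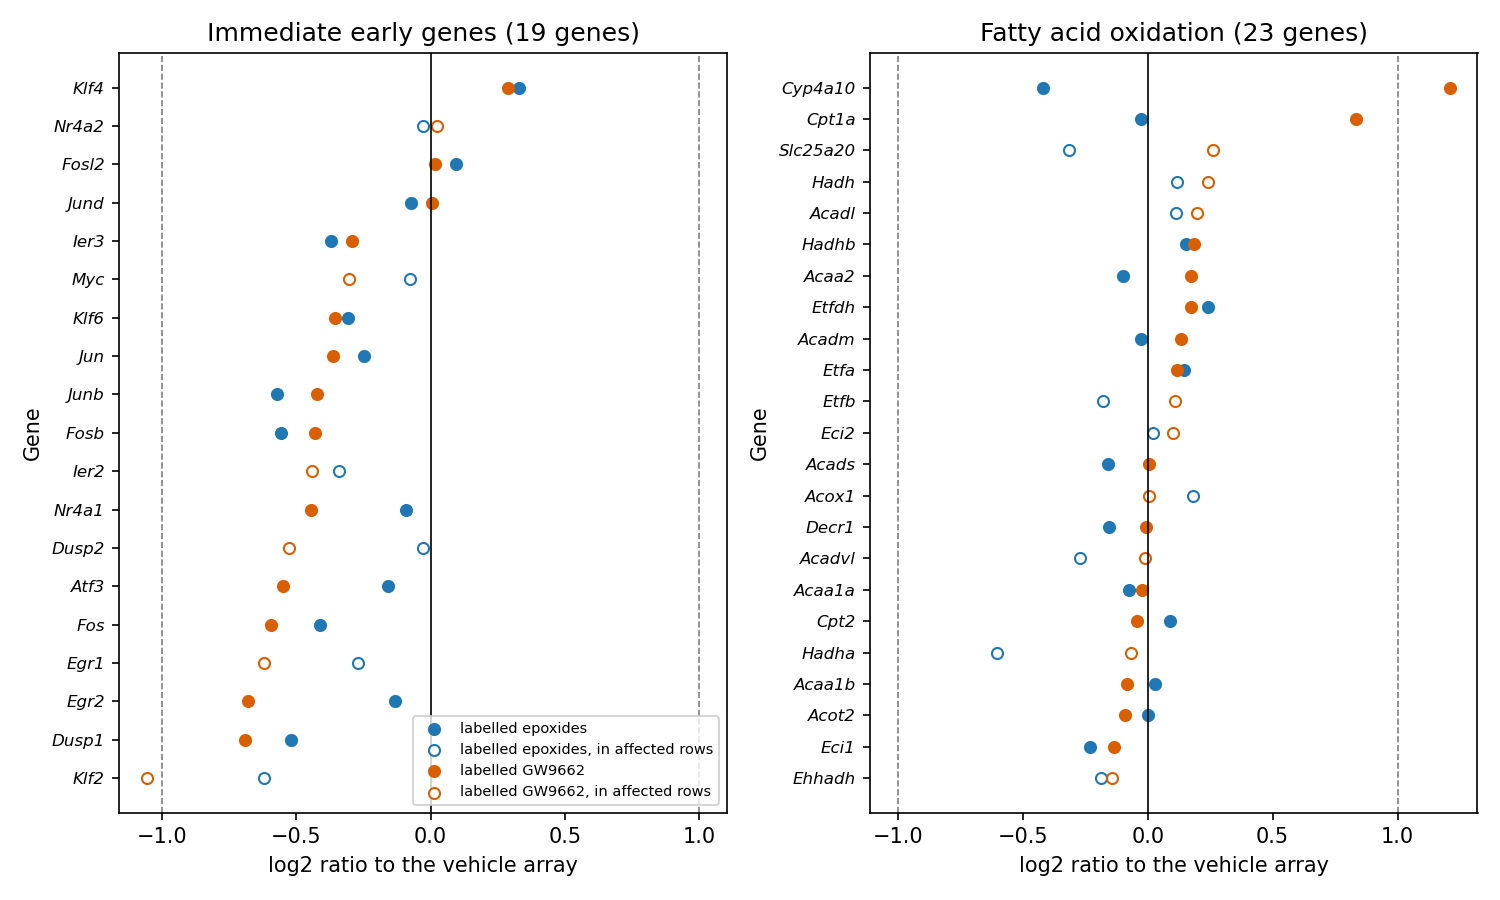
Log2 ratio to the vehicle array of the 19 immediate early genes and the 23 fatty acid oxidation genes above background on all 3 arrays, for the array labelled epoxides (blue) and the array labelled GW9662 (orange). Open circles are genes read in rows 181 to 400, and dashed lines mark a 2-fold difference. Klf2 at -1.06 and Cyp4a10 at 1.21 are the points beyond the dashed lines, both on the array labelled GW9662.

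Over the 15795 genes measured on both arrays, 56 were at least 2-fold higher and 74 at least 2-fold lower on the array labelled GW9662. All but 3 of these, 53 higher and 74 lower, were read in rows 181 to 400. The 3 others, named after their values were seen, were BC052040 (1.07), Cyp4a10 (1.21) and Pdss2, an enzyme of coenzyme Q synthesis (1.53). Further probes did not follow for some genes: other detected probes had ratios of -0.20 for Cyp4a10, -0.20 for Cyp4a31 and -0.15 for Pdss2, while the second Cpt1a probe had 1.08. All of these were dim with vehicle, at -3.94, -3.48, -4.19 and -3.58, and all but that of Pdss2 were read in rows 181 to 400. Probes of Cyp4a10 and Cyp4a31 not above background on any array had -0.20 and -0.21. Ratios near -0.20 may thus be those of background and do not decide on the rise. Cyp4a31, also chosen after its value was seen, had 1.44, but its probe and that of Cyp4a10 share a run of 27 bases, so they do not count as separate readings. In the authors' value table the column labelled GW9662 gives -0.021 for Cyp4a12a and -0.42 for Cyp4a10, and the column labelled epoxides carries the rise.

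The third comparison set the treatments side by side. On the array labelled epoxides, Cyp4a12a and Cyp4a12b were lower than on the array labelled GW9662, with log2 ratios of -1.55 (2.94-fold) and -1.39 (2.62-fold), and Cpt1a had -0.86. Against vehicle the array labelled epoxides had -0.021, 0.006 and -0.026 for these genes. The differences are thus the rise on the array labelled GW9662 given above and no separate finding. Immediate early genes had a median of 0.12 over 19 genes (percentile 99.96), with Egr2 at 0.55, the MAP kinase phosphatase Dusp2 at 0.50, Klf2 at 0.44 (read in rows 181 to 400) and the stress factor Atf3 at 0.39. Genes of S phase had a median of 0.07 over 21 genes (percentile 99.5), with thymidine kinase Tk1 at 0.25, the replication factors Mcm2 at 0.24 and Cdc6 at 0.20, and the ribonucleotide reductase subunit Rrm1 at -0.20. Against vehicle, immediate early genes and S phase had medians of -0.20 and -0.05 on the array labelled epoxides. On the array labelled GW9662 they had -0.43 and -0.10. With this scaling their positive medians here are thus no rise over vehicle on the array labelled epoxides. Negative regulators of the IgE receptor and of Src kinases had a median of 0.06 over 29 genes (percentile 99.7), with Dusp2, the signalling inhibitor Spry2 at -0.48, Csk at 0.36 and Cd300a at 0.32. Without rows 181 to 400 the ratios of this list ran from -0.24 to 0.36, so those of Dusp2 and Spry2 rest at least partly on those rows. Markers of neutrophils and their precursors had a median of -0.48 over 6 genes (percentile 2.02), with the granule proteins Mpo at -2.997, Camp at -0.66, Lcn2 at -0.51 and Elane at -0.44. These were 4 of the 36 lists placed. In the simulated data for the comparisons with vehicle, 5 and 10 of 100 unshifted lists lay outside the middle 95%. Mpo was read in rows 181 to 400, and the neutrophil markers lay at percentile 19.3 with no filter on dim probes. Only 2 of these markers were at or above the median signal. Outside those rows, the dimmest of 10 signal bins had a median of -0.24 (first quartile -0.50), so a shift at low signal may be part of the neutrophil median. Inside the middle 95% came S phase with normexp (97.0) and quantile normalization (97.2), and the negative regulators with the trend in GC content and signal removed (94.5), among genes at or above the median signal (96.9) and without rows 181 to 400 (97.2). With cyclic loess the medians were 0.18 for immediate early genes, 0.14 for S phase and 0.11 for negative regulators, and with the trend removed that of the neutrophil markers was -0.29.

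Over the 16048 genes measured on both arrays, 33 were at least 2-fold higher and 154 at least 2-fold lower on the array labelled epoxides. The genes higher made up 17.6% of these calls, 38.9% with quantile normalization and 33.3% with cyclic loess. With rows 181 to 400 left out and the trend with GC content and signal removed, 14 genes were higher and 6 lower. Every ratio of this comparison changes sign where the value table's columns are used.

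Across the 15698 genes above background on all 3 arrays, 58 were at least 2-fold lower and 1, the histone methyltransferase gene Smyd3, was higher than vehicle on both treated arrays. All 58 were read in rows 181 to 400. Mrrf, Hist2h3c2, 2210417A02Rik and the transcript ENSMUST00000118274 differed in opposite directions, also in these rows, and these 5 genes were named after their values were seen. Lists independent of each other would share 1.22 lower and 0.105 higher genes, but both ratios use the same vehicle array. With the array labelled epoxides as the shared one, 61 genes differed alike, and with the array labelled GW9662, 41. In 20 simulated sets of unchanged arrays, between 91 and 121 genes differed alike, more than measured, and these sets also gave more genes higher than measured in each comparison. The log2 ratios to vehicle had r = 0.565 across genes, which are not independent replicates, and r of 0.485 to 0.556 in the simulated sets. The covariance was 0.0423 with vehicle shared, 0.0786 with the array labelled epoxides shared and 0.00403 with the array labelled GW9662 shared.

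Genes above background on 1 of a pair of arrays give only a bound on their ratio. Srcin1, an adaptor that holds back Src kinase activity, was above background on the vehicle array only, at least 9.86-fold over the array labelled epoxides and at least 6.78-fold over the array labelled GW9662. These bounds ranked 24 and 20 among plain gene symbols. The largest for vehicle were those of Olfr933, an olfactory receptor gene (at least 22.4-fold and 15.4-fold), Clca4a (20.6-fold and 14.1-fold) and the keratin Krt6a (19.4-fold and 13.3-fold). The largest for the array labelled epoxides over vehicle were those of Rab11fip1, a partner of the GTPase Rab11 (10.7-fold), the vomeronasal receptor gene Vmn1r66 (10.5-fold) and the ion channel gene Calhm1 (10.4-fold). Over the array labelled GW9662, these 3 had bounds of 12.2-fold, 11.9-fold and 11.8-fold. The largest for the array labelled GW9662 over vehicle were those of the scaffold gene Magi1 (17.4-fold), the autophagy receptor gene Calcoco2 (16.5-fold) and Olfr270 (11.7-fold). Over the array labelled epoxides they were Calcoco2 (27.3-fold), Olfr270 (19.4-fold) and the transporter gene Slc17a2 (19.4-fold). Of the 388 genes bounded at 2-fold or more for vehicle over the array labelled epoxides, 91.5% were read in rows 181 to 400, as were 97.7% of the 221 for vehicle over the array labelled GW9662. For the array labelled GW9662 the shares were 96.4% of 165 over vehicle and 93.9% of 309 over the array labelled epoxides. For the array labelled epoxides they were lower, 75.2% of 109 over vehicle and 70.1% of 107 over the array labelled GW9662. Of the genes named here with bounds, all except Krt6a were read in these rows. The Srcin1 probe lies in row 297, and a second Srcin1 probe was not above background on any array.

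**Figure D3:**
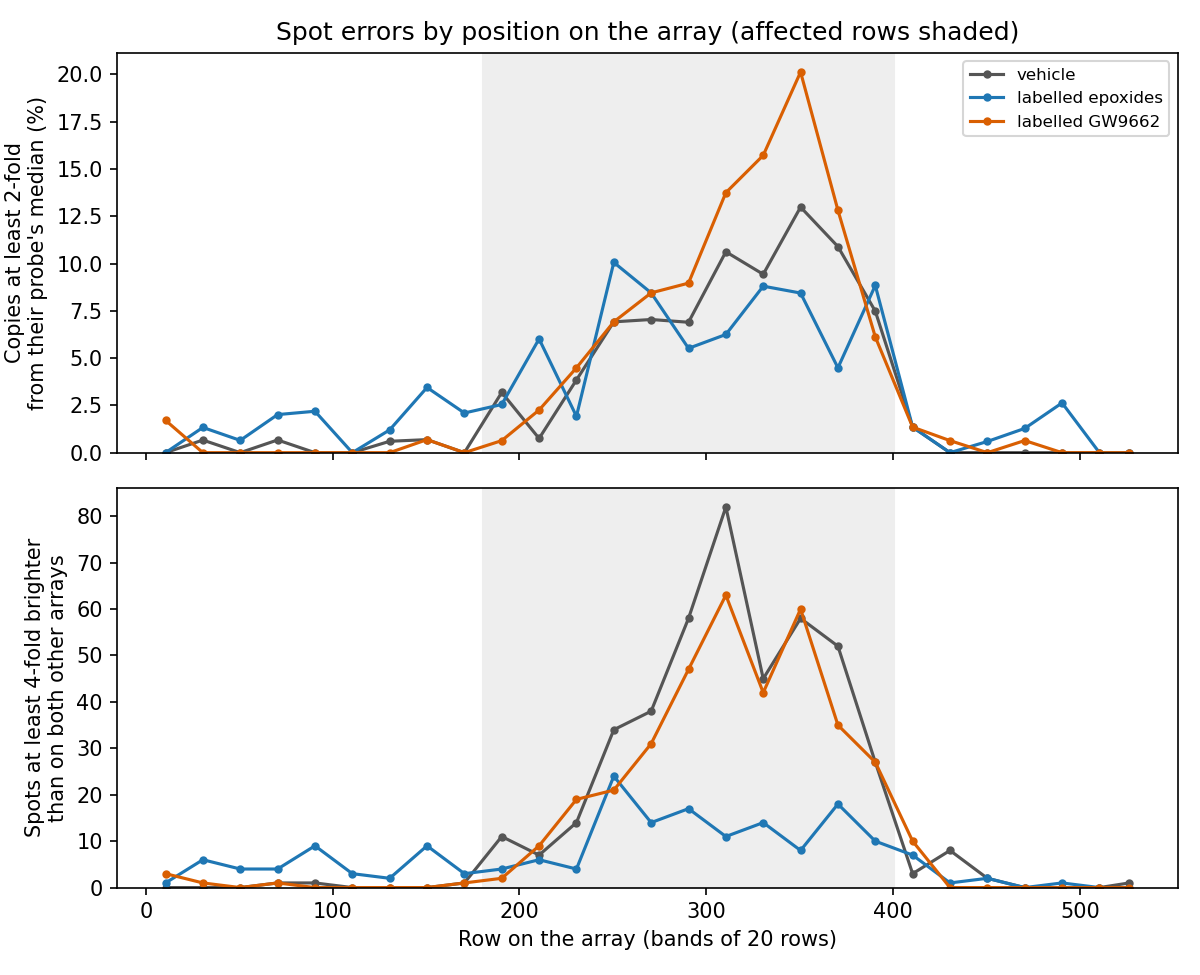
Percentage of probe copies at least 2-fold from the median of their probe (top) and number of spots at least 4-fold brighter on 1 array than on both others (bottom), by bands of 20 rows, for each of the 3 arrays. Both rise in the shaded rows 181 to 400, which hold 96.2% of the 443 spots bright on the vehicle array only, 95.7% of the 372 bright only on the array labelled GW9662 and 71.4% of the 182 bright only on the array labelled epoxides.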

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

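The alternatives without rows 181 to 400 and with the trend in GC content and signal removed were chosen after the data were seen, and the others before. No paired analysis was possible because each group has 1 array. Counts of genes moved by over 1.5 times under most alternatives, and scaling on probes above background on all arrays and averaging a gene's probes left all 10 main results within that range. Of the 21 list medians described, 5 changed sign with the authors' value table and 4 with at least 1 other alternative (12 values of 207), all 4 for epoxides over vehicle: mast cell identity, IgE receptor signalling, negative regulators and PPAR gamma targets. Of 98 single-gene ratios, 35 changed sign with the value table and 5 with at least 1 other alternative (9 values of 842), namely Plin4 and Kit for epoxides over vehicle, Fcer1g for GW9662 over vehicle, and Kit and Ms4a2 for epoxides over GW9662. The number of list medians outside the middle 95%, summed over the 3 comparisons, stayed within 1.5 times, but not in each: for epoxides over GW9662 it went from 4 to 8 with the trend removed, 7 with no filter on dim probes and 2 without rows 181 to 400 or among genes at or above the median signal. For epoxides over vehicle it went from 0 to 3 with rows left out and the trend removed.

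Value table aside, 4 lists for GW9662 over vehicle and 3 for epoxides over GW9662 came inside under at least 1 alternative. For GW9662 over vehicle, hypoxia and glycolysis did so with cyclic loess (percentile 4.28) and the mean of a gene's probes (13.2), G2 and M phase among genes at or above the median signal (96.5), and cytokines and chemokines with no filter on dim probes (2.78). For epoxides over GW9662, S phase did so with normexp (97.0) and quantile normalization (97.2), and negative regulators among genes at or above the median signal (96.9) and without rows 181 to 400 (97.2). In the other direction, 6 lists for epoxides over vehicle came to lie outside. They were immediate early genes among genes at or above the median signal (0.08), ribosomal proteins with no filter on dim probes (0.24), neutrophil markers with normexp (2.00), PPAR and RXR family genes without rows 181 to 400 (1.52), G2 and M phase with the trend removed (99.9), and granule proteases with both changes (1.89). For epoxides over GW9662, 9 lists did so, among them fatty acid oxidation (0.41), NRF2 response (0.56), hypoxia and glycolysis (98.8) and T and NK cell markers (1.48) with the trend removed, and the ER stress response with quantile normalization (98.3). For GW9662 over vehicle, macrophage markers did so without rows 181 to 400 (97.6). Signal over background limits the dim genes, and without the filter on them the counts rose the most. Neutrophil markers had too few genes for a median without rows 181 to 400 or among genes at or above the median signal. Except for the value table, where exchanged columns give the moves, and for settings that run fewer or more genes, the cause was not tested.

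Counts are given as higher and lower for epoxides over vehicle, GW9662 over vehicle and epoxides over GW9662. With normexp, epoxides over vehicle had 16 and 128 genes, GW9662 over vehicle 49 lower, and epoxides over GW9662 16 and 71; 37 genes differed alike. With quantile normalization, epoxides over vehicle had 63 and 141, and epoxides over GW9662 56 and 88. With cyclic loess these were 55 and 185, and 51 and 102. With no filter on dim probes the counts were 594 and 2381, 971 and 1077, and 573 and 1860, with 1060 alike and r = 0.511. With only genes at or above the median signal they were 3 and 15, 2 and 1, and 1 and 6, with 0 alike and r = 0.613. At 1.5-fold they were 212 and 1400, 110 and 181, and 152 and 771, with 146 alike.

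Without rows 181 to 400 the counts were 13 and 118, 3 and 0, and 9 and 16, with 0 alike and r = 0.680. With the trend in GC content and signal removed, epoxides over vehicle had 57 and 125 and epoxides over GW9662 50 and 95, r was 0.536 and the Pafah2 ratio for epoxides over vehicle was -0.22. With both, the counts were 22 and 20, 3 and 0, and 14 and 6, with 0 alike.

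With the authors' value table the counts were 56 and 74, 34 and 328, and 154 and 33, and the Pafah2 ratio for epoxides over vehicle was 0.037. For GW9662 over vehicle the fatty acid oxidation median became -0.028, Cyp4a12a -0.021 and Cyp4a10 -0.42. For epoxides over GW9662 the medians became -0.12 for immediate early genes, -0.069 for S phase, -0.063 for negative regulators of the IgE receptor and Src kinases and 0.48 for neutrophil markers, and the genes became 1.55 for Cyp4a12a, 1.39 for Cyp4a12b and 2.996 for Mpo.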

Other observations

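All tests in this part were chosen after the results were seen. Outside rows 181 to 400 and with the trend in GC content and signal removed, the 6 most negative ratios of bright genes on the array labelled GW9662 were those of Dusp1 (-0.71), Csrnp1, a nuclear protein (-0.64), Fos, an AP-1 subunit (-0.63), Rasa1, a GTPase-activating protein for Ras (-0.60), Plk3, a polo-like kinase (-0.50), and the long non-coding RNA Malat1 (-0.46). Cpt1a had the highest ratio, 0.87, and the next, Zfp87, had 0.34. On the array labelled epoxides, low ratios of this kind included Kdr (-0.95) and Prss53 (-0.75), and the highest were those of Fam219a (1.08), Ralgps1 (1.01) and Hpca (1.003), which had 0.82, 0.73 and 0.66, less than 2-fold, before the trend was removed.

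The 58 genes lower than vehicle on both treated arrays would be of interest as a shared response. Of them, 100% were read by spots in rows 181 to 400, against 42.2% of all genes above background on the 3 arrays, and 0 lay outside, where 79.4 would be expected at the rate inside. This argues against an effect of both treatments as the source of the set, and local spot errors in these rows are a candidate explanation. Single genes of the set stay open.

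Many genes were lower on the array labelled epoxides than with vehicle, and the ratios spread widely. Of 118 genes at least 2-fold lower outside rows 181 to 400, removing the trend in probe GC content and signal left 20 (83.1% fewer), but methods that use no GC content also left fewer: 64 with each array only shifted, 56 with cyclic loess, 42 with quantile normalization and 29 with normexp. A trend in GC content alone left 30, 53.1% fewer than the shift, and one in signal alone 46, 28.1% fewer, which is consistent with GC content as 1 source among others of the lower calls and leaves the part of signal open (these falls were first computed from 118, as 74.6% and 61.0%, which counts the shift in). With the trend in both removed, 77.6% of the SD of the log2 ratios outside those rows was left and the genes at least 2-fold higher went from 13 to 22, and local errors in those rows are not the whole source, since the SD outside them was 89.6% of that over all genes. An effect of the treatment stays untested, since array and treatment are the same split.

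Higher Cpt1a and Cyp4a signal on the array labelled GW9662 may reflect a real transcript difference. Local errors in rows 181 to 400 are argued against for Cpt1a, whose 6 copies outside them had a median log2 ratio of 0.86, with 10 copies in all running from 0.78 to 0.91. The Cyp4a10 spot, with a ratio of 1.21, lies in row 475, outside those rows. This was known when the gene was taken up, so it is no further test. The other 3 Cyp4a spots lie in those rows, with a median pixel CV of 0.098 (0.061 to 0.141) on that array. In 54 other spots there that were at least 2-fold brighter on it only, the median was 0.26, and 2 of them were at or below 0.141. These 54 were not matched on signal, so the lower pixel CV does not decide on local errors. Of the 56 genes at least 2-fold higher on this array, 2 were left among genes at or above the median signal. Errors of single spots elsewhere on the array were not tested. The fitted trend is too small to give such ratios, since its medians by GC content ran only from 0.03 to -0.11 in this comparison. Its removal took the median of the 5 genes from 1.40 to 1.39, which is no further test. The probes of Cyp4a10 and Cyp4a31 share a run of 27 bases. Other detected probes of these genes, dim and in rows 181 to 400, had -0.20, which does not decide on the rise. The treatment itself stays open, because the value table gives the same signals to the epoxide sample.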
